A study of Drosophila melanogaster with 4 samples.

How the data were processed

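Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on RNA polymerase II (Pol II), the enzyme that transcribes protein-coding genes, in whole embryos of *Drosophila melanogaster*. The embryos were of the wild-type Oregon-R strain and 14 to 16 h old. Per the labels' protocols, embryos were crosslinked with 1.8% formaldehyde, the chromatin was precipitated with a commercial antibody (abcam), and the bound DNA was purified. The series had 4 samples, namely 2 ChIP libraries and 2 input libraries of chromatin DNA. Each input served one of the ChIP libraries, per the labels. The inputs enter here only through the authors' calls, and no values of their own were analysed here.

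Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes, to FlyBase release 5, per the file headers. The authors then listed regions of significant enrichment, one list for each ChIP replicate and one list for the replicate set as a whole, called the whole-series list below. The region caller, its threshold, and the way the replicates were joined for the whole-series list are not given in the sources used here. Each row gave the first and last base of a region, counted from 1, and a score per region that the authors deposited. The score is the authors' own value. Its formula is not given in the sources used here, but its scale could be read from exact ties. Among the 190 differences between the 20 most often repeated scores of replicate 1, 50 equalled the base-2 logarithm of a ratio of whole numbers up to 32, within 1e-06. None matched on the natural or base-10 scale. The corresponding counts were 46 in replicate 2 and 28 in the whole-series list. Scores are therefore given as values on a log2 scale, of a ratio whose denominator is not stated, and are used only to rank, describe or filter regions within a list, apart from the correlation between replicates.

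Sequencing depth is unknown, since the lists hold no read counts. Intervals on shares of regions are Wilson 95% intervals and cover counting error only. The labels do not say whether the 2 ChIP replicates came from separate embryo collections, so spreads between them may be technical. Means are given with the SD over the 2 replicates.

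Lists were compared by overlap of at least 1 bp. Chance overlap was taken from 1000 circular shifts of one list within each chromosome, as a one-sided permutation test whose smallest possible p is 0.000999. Scores of overlapping pairs, each region used once, were compared by Spearman and Pearson correlation across regions. Scores of region classes were compared by a two-sided permutation test with 100000 resamples, whose smallest possible p is 1e-05. Regions are not independent replicates, and neighbouring regions can depend on each other. For the X against the autosome arms, median scores of 1 Mb blocks were permuted, and intervals came from 2000 bootstrap draws of blocks. Positions along the 5 major arms (2L, 2R, 3L, 3R and X) were counted in 500 kb bins by region midpoint, and clustering in 100 kb bins was compared with 1000 random placements. The overlap test was tested on simulated data in which none, 20% or 60% of the 5192 regions of replicate 1 were planted in a second list. It found 17.6%, 32.2% and 62.9% overlap against 18.2%, 31.7% and 63.0% expected, and the planted lists alone passed the threshold. The expected values used the mean overlap after shifting in the same runs, so they are not a separate check. These runs used fewer shifts. Planted regions were exact copies and the rest were placed at random, without the clustering and edge differences of the real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

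The comparisons, the alternatives and the rule for named regions were fixed before the data were examined, with exceptions. The comparison of scores between the X and autosomes, the centromere-proximal density, the clustering test and the bin correlation were chosen later. So were the score classes, the split of the whole-series list by replicate overlap and the longest stretches free of regions. Alternatives to these were also chosen later, as were those for whole-series overlap and the major-arm setting for one-replicate regions. The rule named the 10 highest-scoring and the 10 widest regions of the whole-series list that both replicates share, and the 3 highest-scoring regions of each replicate with no partner in the other. Tests against gene annotation and on 32 gene lists had also been planned. They were not run, because the gene table at hand is on release 6 and coordinates were not converted between releases. Regions are therefore given by position, without gene names, exons or introns.

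Alternatives were a reciprocal overlap of 50%, extension of regions by 500 bp, merging within 500 bp, regions at or above the median score, major arms alone, other bin sizes, and leaving out each replicate. The extension was applied on each side to the regions of the other list only.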

Results

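The data were lists of Pol II-enriched regions from 2 ChIP-seq replicates of 14 to 16 h Oregon-R embryos, each with its own input library per the labels, and one list for the replicate set. By this age the main body plan is laid down and tissues such as muscle, nervous system and epidermis are differentiating. The lists record where along the chromosomes Pol II was enriched in the whole embryo, with all tissues mixed. Replicate 1 held 5192 regions and replicate 2 held 5199. The whole-series list held 9885. Read depth is unknown, so the lists cannot show whether a stretch without a region lacked Pol II or lacked reads.

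Pol II regions were short and spread over all major chromosome arms. They covered 10.2% ± 0.1 (SD, n = 2) of the 119 Mb of arms 2L, 2R, 3L, 3R and X, and 98.7% ± 0.1 (SD, n = 2) of regions lay on these arms. The median region was 2044 bp ± 17 (SD, n = 2) wide. In replicate 1, 85.2% of regions were at most 3 kb wide and held 70.2% of the covered bases. In replicate 2 the same shares were 85.0% and 70.1%. Regions wider than 10 kb were few, 29 in replicate 1 and 31 in replicate 2, and all of them overlapped a region of the other replicate. The narrowest region was 1301 bp in both replicates and 1001 bp in the whole-series list. Regions were separated by a median gap of 9171 bp ± 38 (SD, n = 2).

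Arm 2R had the highest density of Pol II regions among the major arms, by more than the spread between replicates, with 51.0 regions per Mb ± 0.7 (SD, n = 2). Arms 3R and 3L followed with 43.2 ± 0.4 and 42.4 ± 0.5 (SD, n = 2), then the X with 40.2 ± 0.5 and 2L with 39.2 ± 0.3 (SD, n = 2). In the whole-series list the X, with 80.7 regions per Mb, stood above 3L, with 78.0. Regions of the replicates covered 12.3% ± 0.02 of 2R and 9.02% ± 0.14 of 2L (SD, n = 2). The fourth chromosome, a small chromosome known for its mixture of genes and heterochromatin, had 31.4 regions per Mb ± 1.6 (SD, n = 2), which was 0.73 ± 0.04 times the density of the major arms. Among regions at or above the median score of each list, this ratio was 0.36. Densities are compared with the replicate spread alone.

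Heterochromatin, the compact and repeat-rich chromatin near centromeres and on the Y, held few Pol II regions. The 6 scaffolds assigned to heterochromatin (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet) total 9.28 Mb and held 17 regions in replicate 1 and 18 in replicate 2. Their density was 1.89 regions per Mb ± 0.08 (SD, n = 2). The major arms were 22.9 ± 0.9 times denser (SD, n = 2). This ratio was 13.8 in the whole-series list and 40.2 among replicate regions at or above the median score. On the unplaced sequence U, 10.0 Mb long, each replicate listed 6 regions. On Uextra no list held a region. On YHet the replicates listed none, and the whole-series list held 1 region. Reads from repeats may map to several places, and how the authors treated such reads is not given in the sources used here.

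**Figure D1:**
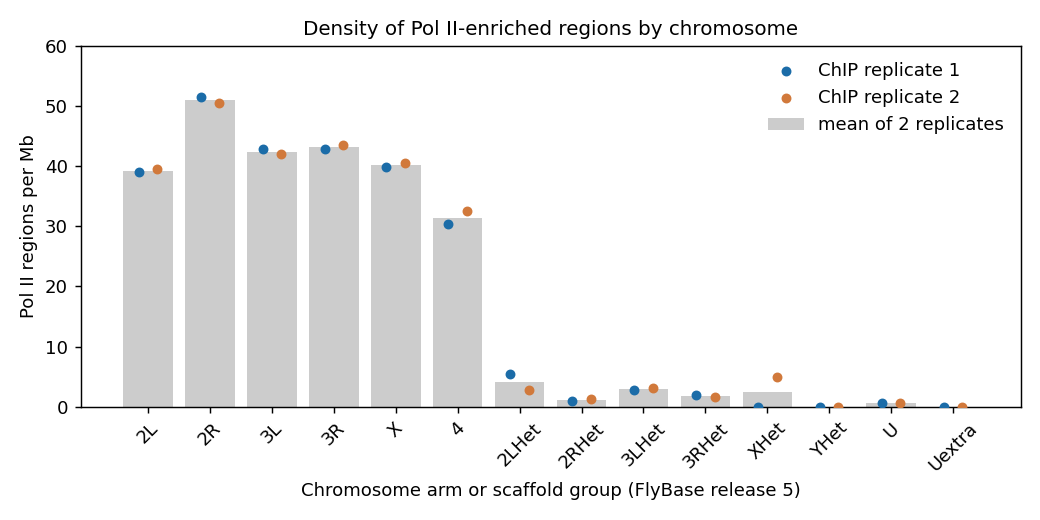
Pol II regions per Mb (vertical axis) for each chromosome arm or scaffold group of FlyBase release 5 (horizontal axis). Grey bars are the mean of the 2 ChIP replicates and coloured points are the replicates. The major arms lie between 39.2 and 51.0 regions per Mb and the fourth chromosome at 31.4, while the heterochromatin scaffolds together have 1.89.

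Within the arms, Pol II regions thinned out towards the centromere end of most arm sequences. Distance to the centromere was counted from that end. In the nearest 2 Mb, density was 0.53 ± 0.05 times that of the rest of the arm (SD, n = 2) over the 5 major arms together. On 3L there were 9.75 ± 1.06 regions per Mb near the centromere against 45.3 ± 0.7 elsewhere (SD, n = 2). On 2R the values were 15.5 ± 4.2 and 54.7 ± 1.2, on the X 15.8 ± 2.5 and 42.6 ± 0.3, and on 2L 23.5 ± 0.0 and 40.7 ± 0.3 (SD, n = 2). Arm 3R went the other way, with 53.5 ± 3.5 regions per Mb at this end against 42.4 ± 0.2 in the rest of the arm (SD, n = 2). The 2.52 Mb of 3RHet, a separate sequence, held 5 regions in replicate 1 and 4 in replicate 2. Heterochromatin scaffolds are not part of the arm sequences, so a dense arm end does not show that regions are dense beside the centromere. Both 500 kb bins between 23500001 and 24500000 of 3L were empty in both replicates. The whole-series list held 6 regions in the first of them and 1 in the second.

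The same stretches were dense or sparse in both replicates. Across 236 bins of 500 kb, the numbers of regions correlated with a Spearman rho of 0.91 and a Pearson r of 0.92 (permutation p = 1e-05 for rho, the smallest possible; bins are not independent replicates). The median bin held 21 regions. The densest bins were 2R from 3500001 to 4000000, with 44 and 47 regions in replicates 1 and 2, and 3L from 3000001 to 3500000, with 45 and 46. Next came 2L from 5000001 to 5500000, with 43 and 46. Regions were clustered. The variance of the number of regions per 100 kb bin was 2.14 times its mean in replicate 1 and 2.19 times in replicate 2, against at most 1.21 in 1000 random placements (permutation p = 0.000999 in each). Bins with no region made up 9.08% and 7.57% of the 1189 bins, where a random spread would leave 1.34%.

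**Figure D2:**
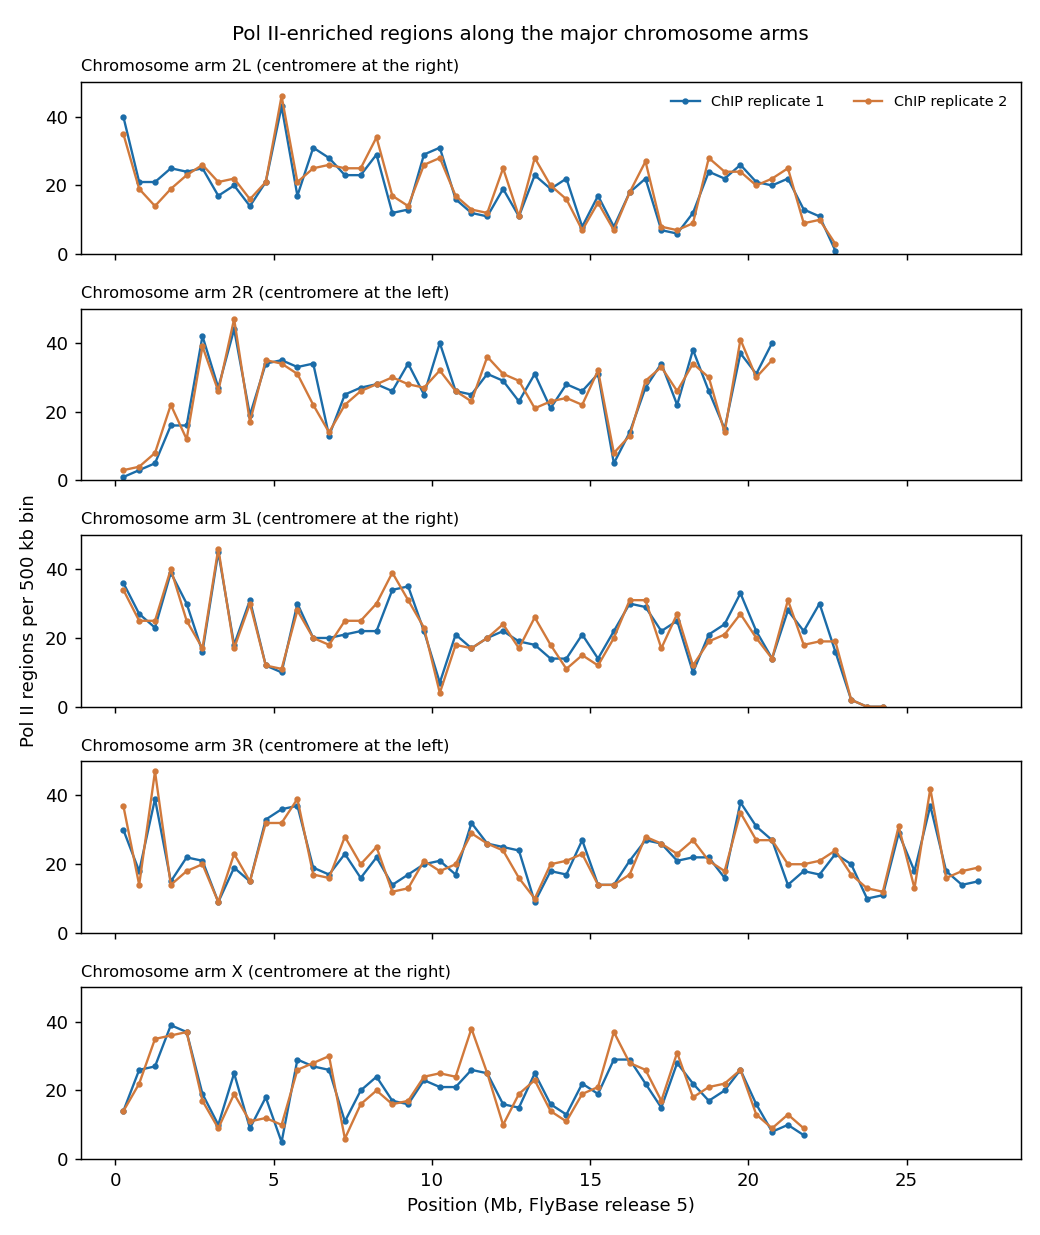
Number of Pol II regions per 500 kb bin (vertical axis) along each major arm (horizontal axis, Mb, FlyBase release 5), with one line per ChIP replicate. The lines of the 2 replicates run together. Counts fall towards the centromere end of the arm sequence on 2L, 2R, 3L and X but not on 3R. On 3R the 2 Mb nearest that end hold 53.5 regions per Mb.

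The X and the autosomes were set side by side because male flies have a single X whose transcription is raised by the dosage compensation machinery. The X had 40.2 regions per Mb ± 0.5 and the 4 autosome arms together 43.8 ± 0.1 (SD, n = 2), a ratio of 0.92 ± 0.01. In the whole-series list the ratio was 0.987, with 80.7 and 81.8 regions per Mb. Among regions at or above the median score of each list, a filter that favours the X because its scores were higher, the ratio turned to 1.25. Median widths of X and autosome regions were 2027 and 2037 bp in replicate 1 and 2028 and 2063 bp in replicate 2. X regions scored higher. The median score was 0.77 on the X and 0.68 on the autosome arms in replicate 1, and 0.74 and 0.68 in replicate 2. The difference was 0.09 in replicate 1 (95% block bootstrap interval 0.07 to 0.11) and 0.07 in replicate 2 (interval 0.05 to 0.09). The permutation test used median scores of 1 Mb blocks, 23 on the X and 97 on the autosome arms. The difference of block medians was 0.087 in replicate 1 (permutation p = 1e-05) and 0.064 in replicate 2 (permutation p = 2e-05). The autosome arm with the highest median score was 2R in both replicates, at 0.69 in each.

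The replicates placed most of their Pol II regions at the same positions. Of the replicate 1 regions, 4013 of 5192 (77.3%, Wilson 95% interval 76.1 to 78.4) overlapped a replicate 2 region. Of the replicate 2 regions, 4006 of 5199 (77.1%, interval 75.9 to 78.2) overlapped a replicate 1 region. Circular shifts gave 18.97% ± 0.7 (SD over shifts) and never more than 30.4% for replicate 1 (permutation p = 0.000999, the smallest possible). The bases shared by both lists were 0.594 of all bases covered in either, against 0.0539 on average after shifting. Under a reciprocal overlap of 50%, 69.5% of replicate 1 regions and 69.4% of replicate 2 regions had a partner. Edges of overlapping pairs differed little at the median. Over 3877 region pairs, chosen for the most shared bases, starts differed by a median of 89 bp and ends by 86 bp. Widths of these pairs correlated with a Spearman rho of 0.65. Scores of these pairs correlated with a Spearman rho of 0.77 and a Pearson r of 0.84 (permutation p = 1e-05 for rho; this correlation is across regions, which are not replicates).

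Regions called in one replicate only were narrower and scored lower than shared ones. There were 1179 of them in replicate 1 and 1193 in replicate 2. Their median width was 1561 bp against 2116 bp for shared regions in replicate 1, and 1601 bp against 2122 bp in replicate 2. Their median score was 0.63 against 0.74 in replicate 1 and 0.59 against 0.75 in replicate 2. A region of replicate 1 only scored below a shared region with a probability of 0.685, and in replicate 2 this was 0.734 (permutation p = 1e-05 in each). In the top score class, which holds 520 regions of each list, 99.6% of replicate 1 regions and 99.4% of replicate 2 regions had a partner. The fewest partners were found in the third class from the bottom in replicate 1, at 62.6%, and in the second class in replicate 2, at 59.0%.

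**Figure D3:**
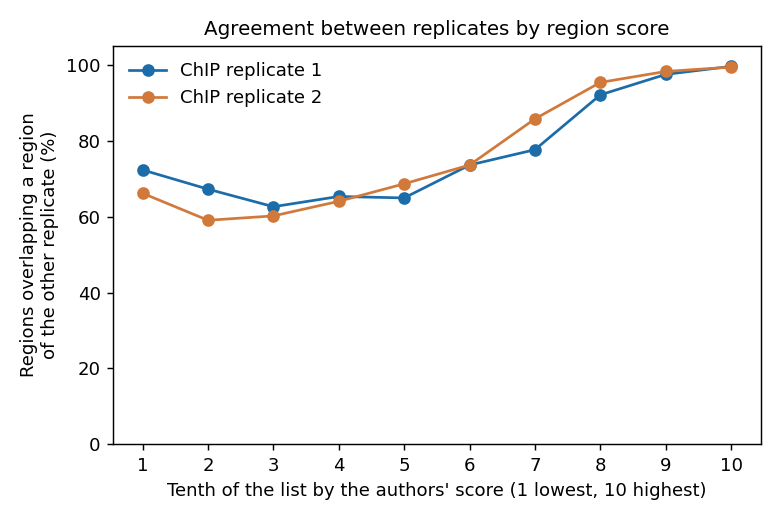
Share of regions (vertical axis, percent) that overlap a region of the other replicate, for 10 classes of equal size ordered by the authors' score (horizontal axis), one line per ChIP replicate. The share reaches 99.6% and 99.4% in the top class and is lowest at 62.6% and 59.0%.

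Of the 10 highest-scoring whole-series regions that both replicates share, 3 lay on 2R, 2 each on 3L, 3R and the X, and 1 on 2L. They were 2.30 to 10.3 kb wide, and 9 of them were a single region in both replicates. The first was 2R from 8866788 to 8869649, which ranked 2 by score in both replicates. It was followed by X from 5233179 to 5235482, ranked 4 in replicate 1 and 7 in replicate 2. Next were 2R from 5436280 to 5446542, ranked 3 and 1, and 2R from 16829790 to 16835304, ranked 5 in both. The fifth was X from 10637328 to 10640802, ranked 6 and 4. The other 5 were 3R from 17121258 to 17126070, 3R from 22464698 to 22468434, 3L from 222076 to 232394, 3L from 3068963 to 3071907, and 2L from 13546689 to 13551301. The region on 3R that starts at 22464698 ranked 81 in replicate 1 and 3 in replicate 2. What these positions hold was not analysed here.

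The 10 widest whole-series regions that both replicates share were 21.5 to 73.1 kb wide, and 6 of them lay on 3R. The widest ran over 73.1 kb of 3R, from 5721135 to 5794223, and was made up of 9 regions in replicate 1 and 8 in replicate 2. The next, 37.5 kb of 3R from 5242639 to 5280169, was 4 regions in replicate 1 and 2 in replicate 2. A 27.4 kb stretch of 2L, from 16765264 to 16792663, was a single region in both replicates, 27191 and 27312 bp wide. The remaining 7 were 2L from 1653127 to 1679513, 2R from 18782230 to 18806335, 3R from 11111173 to 11134378, 3R from 5698268 to 5720336, X from 12552379 to 12574378, 3R from 12064699 to 12086406, and 3R from 5163978 to 5185431. Of the 10, 2 were a single region in both replicates. A gap of 798 bp separated the widest region from the 3R region that starts at 5698268, so their widths depend on how gaps are joined. The widest region ranked only 1716 by score in the whole-series list.

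The whole-series list took in nearly all replicate regions and added many narrower ones. It overlapped 98.9% of the replicate 1 regions (Wilson 95% interval 98.6 to 99.2) and 99.5% of the replicate 2 regions (interval 99.3 to 99.7). This overlap is not independent evidence, since the list stands for the same libraries. Of its 9885 regions, 3737 (37.8%) overlapped both replicates, 2086 (21.1%) overlapped one, and 4062 (41.1%, interval 40.1 to 42.1) overlapped neither. The regions without a replicate region had a median width of 1267 bp and a median score of 0.44, against 2639 bp and 0.67 for those found in both (probability of scoring below one found in both 0.863, permutation p = 1e-05). No replicate region was as narrow as that median of 1267 bp. The narrowest was 1301 bp in the replicates and 1001 bp in the whole-series list, and the part played by this difference was not tested. The list covered 19.2% of the major arms, and the regions without a replicate region made up 5.73 of its 23.2 Mb. The highest scores were an exception, since 9 of the 10 highest-scoring regions of this list overlapped no replicate region and were 1001 to 1077 bp wide. The list joined 2 or more replicate 1 regions in 329 of its regions, and 2 or more replicate 2 regions in 324.

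The 3 highest-scoring replicate 1 regions without a partner were U from 9192897 to 9194285, 3LHet from 1882672 to 1884096, and X from 19689933 to 19691257. The first of them had the highest score of the replicate 1 list, 2.94. The regions on U and the X had no overlap with the whole-series list. In replicate 2 they were U from 9710670 to 9712676, 3L from 5123572 to 5127265, and 2R from 8749863 to 8751390. These ranked 18, 188 and 207 by score in their list.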

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

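The major-arm setting for one-replicate regions, the settings for the whole-series overlap, for score differences of the X, for bin sizes and for the centromere-proximal density were chosen after seeing the data. Of 64 values recomputed under alternatives, 49 kept their direction and size. Among the 49 are the values with a replicate left out. These are only the values of the other replicate, so they test no processing choice. The overlap between replicates stayed far above that of shifted lists under every alternative run. The X density ratio and the X score difference alone changed sides. With regions at or above the median score alone, X density over autosome density turned from 0.92 to 1.25, and the X minus autosome median score turned to -0.034 in replicate 1 and -0.047 in replicate 2. That filter keeps more of the X because X scores are higher. It also selects on the score being compared, so the negative differences do not test the higher X scores over whole lists. Among the regions kept, however, the X median was not higher, so the higher X scores were not shown for the upper part of each list. The same filter left 2598 regions per replicate by construction, raised the median width to 2233 bp, and lowered the covered share of the major arms to 6.24%. It also gave 0.36 for chromosome 4 over the major arms, 40.2 for the major arms over heterochromatin, and 0.44 for the centromere-proximal density over the rest. The centromere-proximal ratio was 0.37 for 1 Mb and 0.68 for 3 Mb. Overlap with the whole-series list fell to 80.7% and 81.9% for replicates 1 and 2 under reciprocal overlap of 50%, a rule that can only lower it. It fell to 94.2% and 96.5% when both lists were cut to regions at or above their median score. That cut left 4943 whole-series regions as possible partners. The cause of the other shifts was not tested. Leaving out each replicate gave 5192 to 5199 regions, a median width of 2033 to 2056 bp, and covered shares of 10.1% to 10.2%. The X over autosome ratio was then 0.91 to 0.93, the chromosome 4 ratio 0.70 to 0.76, the heterochromatin ratio 22.2 to 23.5 and the centromere ratio 0.49 to 0.56. No paired analysis was possible because the input libraries have no values of their own here and the report holds a single group. Overlap between replicates cannot be had with a replicate left out, and the annotation, gene-start, gene-list and gene-body alternatives were not run, for want of a release 5 annotation. Depth is unknown, so what it limits cannot be given.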

Other observations

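The tests of a stricter X threshold and of the widest regions of 3R were chosen only after the results were seen. For the latter, the demand that the grouping also hold after merging was added once both values were known. The bounds of the other tests were written before those tests were run, but after the patterns had been seen.

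Long stretches free of Pol II regions were rare on the major arms. In the union of all 3 lists, 8 stretches were longer than 200 kb and 80 were longer than 100 kb, of which 20 lay within 3 Mb of the centromere end of an arm. The longest was 344 kb of the X from 21502023 to 21845868. More than 3 Mb from the centromere end, the longest was 264 kb of the X from 7237297 to 7501489. It was followed by 184 kb of 3R from 3114835 to 3298487 and 176 kb of the X from 13891593 to 14067778. What these stretches hold was not analysed here.

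The highest scores of the whole-series list came from very small regions without replicate support. Of its 10 highest-scoring regions, 9 were without a region in either replicate, and these were 1001 to 1077 bp wide. No replicate list held a region this narrow, since the narrowest there was 1301 bp. Of the 100 highest-scoring whole-series regions, 28 were without a replicate region. In the replicate lists, 2 and 1 of the 100 highest-scoring regions had no partner. Several of these scores were exactly equal, for example 2.98 at 2R from 650342 to 651342, at 3R from 1984265 to 1985285, and at 2 positions of U. The 9 regions included some on U and 2RHet as well as on 2R, 3R and the X. On U, the 27 whole-series regions had a median score of 1.27, against 0.46 to 0.53 on the major arms. On 2RHet the median was 0.43.

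Regions called in a single replicate may lie near the authors' calling threshold. They scored below shared regions with a probability of at least 0.685 in each replicate. Shared regions had been called in each replicate, so lower scores of the rest were likely under other accounts too. The whole-series list held 95.3% of the one-replicate regions of replicate 1 and 97.9% of those of replicate 2. Of all regions of the replicates it held 98.9% and 99.5%. These shares are not independent evidence, since the list stands for the same libraries. The share with a partner did not rise evenly with the score, however. It was 72.3% in the lowest of 10 score classes of replicate 1 and 62.6% in the third from the bottom, and 66.2% and 60.2% in the same classes of replicate 2, so score alone does not place a region near the threshold. No more than 9.33% of the one-replicate regions gained a partner when the other replicate's regions were extended by 500 bp on each side. Edge shifts of up to 500 bp therefore account for few of them, and larger shifts were not tested. A biological difference between the embryo samples stays open and was not tested.

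The whole-series regions absent from both replicates may in part be weaker regions. They scored below regions shared by both replicates with a probability of 0.863. Shared regions had been called in each replicate, so lower scores of the rest were likely under other accounts too and do not decide. Their median score of 0.44 was not below the 0.43 of whole-series regions found in one replicate, and 9 of the 10 highest scores were theirs, so low score is not the whole account. Placement at random along the arms is argued against by their number per 500 kb bin, which followed that of regions shared by both replicates (Spearman rho 0.604, permutation p = 1e-05, 236 bins). Bins are far wider than regions, so they do not show whether both kinds lie in the same domains. Their median width of 1267 bp was also below that of the narrowest replicate region, 1301 bp.

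X regions scored higher than autosome regions. Separate scaling of each chromosome is argued against, because at least 55.0% of the score values tied between X regions also occurred on an autosome arm in every list. Wider X regions are argued against too, since the X median was higher in all 5 width classes of every list. A few very high X regions could not have produced a difference of medians, so that account needed no test. The excess at the 25th percentile was at least 0.0657 in each replicate, which shows only that lower-scoring regions shared it. At the 95th percentile it was 0.0656 in replicate 1, 0.0012 in replicate 2 and -0.0166 in the whole-series list. Each of these 95% bootstrap intervals included 0, so the higher scores were not shown for the top of the lists. A stricter effective threshold on the X, from fewer X reads in embryos of mixed sex, stays open. The excess at the 25th percentile exceeded that at the 95th by 0.0265 to 0.0786 over the 3 lists, but its bootstrap interval excluded 0 in the whole-series list alone, and among shared regions of replicate 2 the difference was -0.0039. Higher Pol II loading of the X through dosage compensation also stays open, since X coverage of the inputs was not analysed here.

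Of the 10 widest shared regions, 4 lay within 630 kb of 3R, from 5163978 to 5794223. In random draws of 10 shared regions, a share of 0.00065 held as many in 1 Mb. After merging of shared regions within 1 kb, the 10 widest had at most 2 in any 1 Mb, which 0.554 of draws matched. Chance and a real grouping cannot be told apart here. The draws take regions as independent, while 2 of the 4 are 798 bp apart, and merging joins these by construction, so the share after merging does not speak for chance either. Which regions took the place of those of 3R after merging was not examined.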
